A study of Mus musculus with 36 samples.

How the data were processed

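The series measured RNA bound to Ago2 in mouse colonic tumours by Halo-enhanced Ago2 pulldown, a form of CLIP sequencing. Tumours were induced at 8 to 12 weeks of age by an enema of 4-hydroxytamoxifen at 5 mg/ml, and tissue was crosslinked 3 times with UV light at 400 mJ per square centimetre, per the labels' protocols. The 36 samples are 3 libraries (miRNA, mRNA and input control) from each of 12 tumours, 6 labelled WT and 6 labelled G12D, and genotype, library type and batch were taken from the labels. The labels number separate samples but do not say in so many words that each number is 1 mouse, so p-values measure the spread between samples as the labels describe them.

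STAR 2.5.2b, DESeq2 and the builds mm10 and GRCm38 are named in the submitters' processing notes, without their roles. The peak caller is not given in the sources used here. The signal tables hold, for 596 mature miRNAs and 7730 merged peaks, read counts that the authors divided by a size factor per library before they deposited them. The deposited signal columns for peaks name the model and a number but not the library type and were taken as the mRNA libraries. The input-control libraries have no values in the tables used here, so peaks were not set against input. The planned comparison of mRNA with input libraries and the input-adjusted comparison of genotypes were therefore not run, and a peak's signal mixes the level of its RNA with Ago2 binding. The deposited log2 fold changes and the adjusted p-values of the authors' own comparison are named as such wherever they are used. A DESeq2 fit here with batch and genotype returned the same calls as the authors' deposited p-values. The peak lists per genotype carry a score per peak whose unit is not stated per the file headers, and the score was used only to rank peaks within a list. The authors called 1 list per genotype, so lists have no replicates. The authors' annotation gives each peak's gene, region and miRNA seed sites. No genome was at hand, so the planned shuffled sequences were not made and the seed sites are the authors' own. Gene names are those of the annotation, which lacks 145 of the merged peaks, and 76 peaks on the mitochondrial chromosome were 0 in every library. Peaks on paralogs, repeats and ribosomal RNA can share reads, and such values are uncertain.

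Every deposited signal value was a whole multiple of the value of 1 read in its library, within a tolerance of 0.001 reads, for 100% of values, so the reads could be recovered. They came to 289462 to 471587 per miRNA library and to 30607 to 974013 per mRNA library. These sums cover the listed features, not whole libraries. One read was worth 0.482 to 4.53 normalised counts in the mRNA libraries, so low values in shallow libraries are coarse. Reads are not shown to be separate molecules, so intervals cover counting error only, and they do not cover the spread between tumours.

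The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(value + 1) with batch as a covariate, for miRNAs with a mean of at least 10 (284) and peaks with a mean of at least 5 (7527), with Benjamini-Hochberg adjustment at 0.05. The added 1 by itself shrinks the fold changes of low features. The peak fold changes are still not conservative, as their median was 1.33 in limma and 0.854 in DESeq2. Because the values were normalised, count tools were run on the recovered reads as alternatives: edgeR 4.0.16 (quasi-likelihood) called 14 miRNAs and 10 peaks, and DESeq2 1.42.0 called 31 miRNAs and 782 peaks. Lists were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. camera compares a list with all other features, and fry asks only whether its members move one way.

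The 10 miRNA lists were let-7 and miR-98, miR-17-92 and paralogous clusters, miR-200 family, intestinal epithelium, smooth muscle and fibroblast, blood cells, endothelium, oncogene-associated, p53-responsive and tumour suppressor, and Dlk1-Dio3 imprinted cluster. The 11 gene lists were Wnt target genes, MAPK output and feedback, Ras pathway, miRNA machinery, TGF-beta and EMT, let-7 targets, cell cycle, colon epithelium, fibroblast and smooth muscle, leukocytes, and endothelium and nerve. Some members stand in more than 1 list, such as Myc and Ccnd1, and lists with fewer than 5 tested features (1 of miRNAs, 2 of genes) got no list test. Of 46 seed families written in advance, 36 had sites in the authors' annotation and 35 had at least 5 tested peaks. A family's miRNA level is the sum over its members.

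The groups, tests, lists, filters and most alternatives were fixed before the data were examined, as was the rule for named features. The rule takes, among features past the threshold, up to 10 with the largest positive and 10 with the largest negative log2 fold change (mean of at least 100 for miRNAs and 20 for peaks), the 10 most abundant miRNAs and peaks, the members of highest mean and smallest p of each list, the peaks of Ago2 and Apc, and list members past the threshold. Some items that this rule takes in are withheld and are not reported here. Differences in library measures were tested with exact two-sided permutation over all 924 splits of 12 libraries into 6 and 6, and, as an alternative added after the data had been seen, over the 400 splits within batches. Correlations across tumours or families used 100000 permutations, two-sided, for which the smallest p is 1e-05. The relative signal of a family's peaks in a tumour is their mean log2 value, adjusted for the mean of all peaks in that library. Peak sets were compared by overlap of at least 1 base on the same strand, and shares have Wilson 95% intervals.

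The scripts were tested on simulated data. With 6 against 6 libraries drawn from the real means, limma recovered 80% of 30 miRNAs changed by a log2 fold change of 1 and 96.7% of 30 changed by 3, among 284. Among 7527 peaks it recovered 1% of 100 changed by 1 and 81% of 100 changed by 3, so changes of that smaller size in single peaks were mostly not detectable there. The simulation did not vary depth, so it cannot tell low depth from spread between libraries. Alternatives covered the pseudocount (0.5 and 5), the filter, the scaling, the tool, the batch term, each batch alone, a replicate block and leaving out each library. Those that left out WT replicates 5 and 6, weighted libraries, or took factors from the peaks, and several for lists and families, were added after the data had been seen. Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9 was used for the other tests and the plots.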

Results

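The 12 colonic tumours came from C57BL/6 mice in which the tumour suppressor Apc had been deleted from the gut epithelium through a tamoxifen-inducible Cre driven by the Villin promoter. The tumours were of 2 genotypes, called WT and G12D here after the labels, with 6 tumours of each. All tumours expressed Halo-Ago2, a fusion of the miRNA-binding protein Ago2 with a tag that binds covalently to a resin. After UV crosslinking, Ago2 was pulled down with its bound RNA, and each tumour gave 3 libraries, of Ago2-bound miRNA, of Ago2-bound mRNA fragments and of input RNA without pulldown, 36 in all. The labels place 3 WT and 3 G12D tumours in each of 2 batches. The purpose, per the title the submitters gave, was to find the targets of miRNAs in tumours.

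The miRNA libraries were alike in depth, from 289462 to 471587 recovered reads. The mRNA libraries were not. Reads recovered in peaks were 361588, 163111, 250437, 770237, 30607 and 57037 in WT replicates 1 to 6, and 810605, 506261, 125384, 628366, 974013 and 631148 in G12D replicates 1 to 6. In WT replicate 5, 59.8% of the peaks had no read, and in WT replicate 6 the share was 34.01%, against 1.14% to 5.85% in the other 10 libraries. Values of single peaks in those 2 tumours therefore rest on few reads, and the limma and DESeq2 counts for peaks below were also made without them.

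Among the miRNAs bound to Ago2, the most abundant was miR-21a-5p, a miRNA raised in many carcinomas, with 21368 ± 4295 normalised counts in WT and 21263 ± 6236 in G12D (SD, n = 6 each). The other 9 of the 10 most abundant were miR-200c-3p, miR-27a-3p, miR-194-5p, miR-26a-5p, miR-196b-5p, miR-30e-5p, miR-19b-3p, miR-429-3p and miR-200b-3p. These include members of the epithelial miR-200 family and the gut miRNA miR-194. Together the 10 held 31.6% to 38.9% of the normalised counts in the 12 tumours, with 34.7% ± 2.61 in G12D (SD, n = 6). None of the 10 passed the test between genotypes, and their log2 fold changes lay between -0.11 for miR-30e-5p and 0.16 for miR-27a-3p.

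The first comparison asked which Ago2-bound miRNAs differed between G12D and WT tumours. miR-135b-5p, a miRNA known to be raised in colorectal tumours and to target Apc, rose from 1202 ± 487 normalised counts in WT to 2741 ± 755 in G12D (SD, n = 6 each), and 5 of the 6 G12D tumours lay above every WT tumour. miR-218-5p rose from 161 ± 17.2 to 315 ± 77.7, with all 6 G12D tumours above every WT tumour. miR-33-5p, which lies in an intron of the sterol regulator Srebf2, rose from 403 ± 57.7 to 603 ± 74.5, and miR-23a-3p rose from 1895 ± 134 to 2755 ± 649. In the other direction, miR-99a-5p fell from 246 ± 139 to 59.0 ± 13.1 and miR-449a-5p, which shares its seed with the p53-responsive miR-34, fell from 240 ± 122 to 82.1 ± 20.8. All 6 G12D tumours lay below every WT tumour for both. miR-146a-5p and miR-146b-5p, which restrain NF-kappaB signalling, fell from 1809 ± 527 to 1083 ± 289 and from 3708 ± 920 to 2523 ± 521, and all 6 G12D tumours lay below the WT mean for both.

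**Figure D1:**
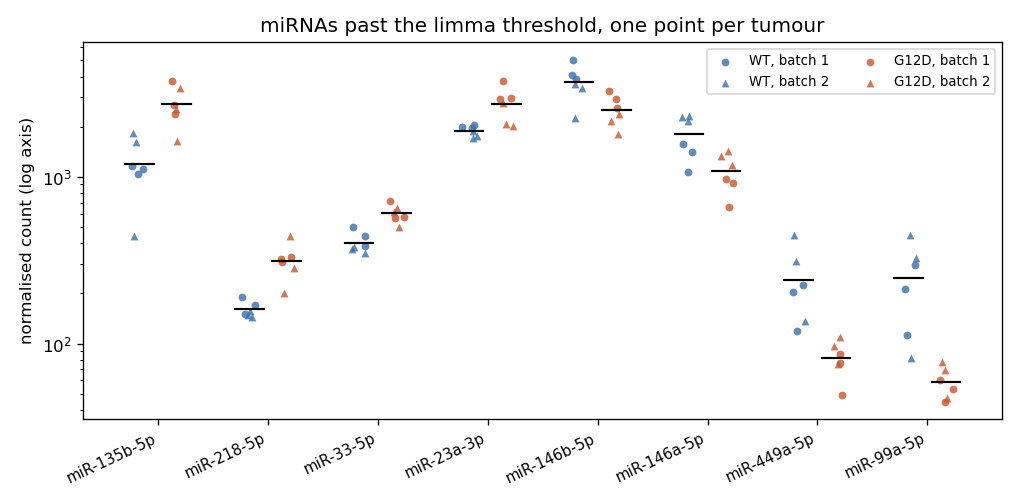
Normalised counts (log axis) of the 8 miRNAs named by the rule fixed in advance, with 1 point per tumour, colours for genotype, circles for batch 1, triangles for batch 2 and black bars for group means. All 6 G12D tumours lie above the WT tumours for miR-218-5p and below them for miR-449a-5p and miR-99a-5p.

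In the limma test with batch as a covariate, 5 miRNAs were higher and 6 lower in G12D at an adjusted p under 0.05, of 284 tested. The log2 fold changes were 1.27 for miR-135b-5p (SE 0.31, adjusted p = 0.0385), 0.93 for miR-218-5p (SE 0.17, adjusted p = 0.0112), 0.58 for miR-33-5p (SE 0.12, adjusted p = 0.0165) and 0.51 for miR-23a-3p (SE 0.11, adjusted p = 0.0189). They were -1.84 for miR-99a-5p (SE 0.37, adjusted p = 0.0163), -1.43 for miR-449a-5p (SE 0.28, adjusted p = 0.0158), -0.73 for miR-146a-5p (SE 0.13, adjusted p = 0.0112) and -0.54 for miR-146b-5p (SE 0.13, adjusted p = 0.0359). The other 3 fell outside the rule for named miRNAs because of low means and were chosen after their values were seen. miR-193a-3p rose from 38.3 ± 9.46 to 104 ± 51.4 (log2 fold change 1.27), miR-148a-5p fell from 79.3 ± 8.70 to 42.4 ± 11.6 (log2 fold change -0.92) and miR-672-5p fell from 82.7 ± 22.1 to 50.3 ± 7.19 (log2 fold change -0.68). Within batch 1 and within batch 2 the log2 fold changes were 1.39 and 1.15 for miR-135b-5p, 0.91 and 0.96 for miR-218-5p, -1.84 and -1.84 for miR-99a-5p, -1.34 and -1.51 for miR-449a-5p, -0.68 and -0.78 for miR-146a-5p and -0.57 and -0.52 for miR-146b-5p. They were 0.49 and 0.68 for miR-33-5p, and lay further apart for miR-193a-3p (0.56 and 1.98), miR-23a-3p (0.68 and 0.34), miR-148a-5p (-1.19 and -0.66) and miR-672-5p (-0.50 and -0.85).

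DESeq2 on the recovered reads gave more calls, 11 higher and 20 lower, and all 11 of the limma calls were among them. The authors' deposited table of miRNAs holds the same numbers of calls, and in the authors' deposited table the calls that limma did not make include miR-708-5p (-1.41), miR-342-3p (-1.19), miR-133a-3p (-1.01) and miR-132-3p (-0.99). Those deposited fold changes were reproduced with a DESeq2 option that draws them toward 0. Without it, DESeq2 gave -1.39 for miR-342-3p, -1.17 for miR-133a-3p and -1.09 for miR-132-3p. Leaving out G12D replicate 6 left 5 calls and leaving out WT replicate 2 left 7, while miR-146a-5p, miR-148a-5p, miR-218-5p, miR-449a-5p and miR-99a-5p stayed past the threshold when any 1 of the 12 tumours was left out. miR-135b-5p stayed in 4 of those 12 fits, miR-146b-5p in 5 and miR-193a-3p in 2. All 3 were lost without WT replicate 2 and without G12D replicate 1, 3, 5 or 6. miR-33-5p was lost without G12D replicate 6, miR-23a-3p without that tumour or WT replicate 2, and miR-672-5p without G12D replicate 4 or 6.

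Of the 10 miRNA lists fixed in advance, 9 had at least 5 members tested. The miRNAs of the Dlk1-Dio3 imprinted cluster, a region expressed in embryonic and mesenchymal tissue, lay lower in G12D as a group. Of 17 tested, 16 had a negative log2 fold change, with a median of -0.45, and none passed the test on its own. Examples are miR-136-5p, at 74.7 ± 27.0 in WT and 51.9 ± 17.8 in G12D, and miR-382-5p, at 17.1 ± 10.1 and 8.47 ± 3.62 (SD, n = 6 each). The list's camera test with a preset correlation of 0.01 between members gave an adjusted p of 0.00569. The adjusted p was 0.789 with an estimated correlation and 0.492 with fry. Its median was -0.70 in batch 1 and -0.28 in batch 2. The list was not past the threshold when G12D replicate 2, G12D replicate 6 or WT replicate 3 was left out.

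Among the miRNAs of blood cells 2 of 7 fell, miR-146a-5p and miR-146b-5p, and 3 were lower when adjusted over the list alone. The added one was miR-342-3p, at 149 ± 63.9 in WT and 56.5 ± 20.3 in G12D. The members did not move together. The leukocyte miRNA miR-142a-3p had 1224 ± 1096 in WT and 1367 ± 757 in G12D, and miR-155-5p had 133 ± 81.7 and 220 ± 85.4. The list median was -0.45 and its camera adjusted p was 0.0934, which became 0.0221 without WT replicates 5 and 6. Over all 12 tumours the adjusted p was 0.748 with an estimated correlation. Among 13 oncogene-associated miRNAs 1 rose (miR-135b-5p), or 2 when adjusted over the list alone, miR-18a-5p being the other with 1145 ± 188 in WT and 1501 ± 71.9 in G12D. The list had a camera adjusted p of 0.433.

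The remaining lists held no miRNA past the limma threshold over all miRNAs, while DESeq2 called miR-18a-5p higher (adjusted p = 0.0143) and miR-133a-3p lower (adjusted p = 0.0201). The let-7 and miR-98 list, a family that restrains growth, had a median log2 fold change of 0.22 over 9 members (camera adjusted p = 0.553), with let-7i-5p at 5630 ± 504 in WT and 5502 ± 554 in G12D. The let-7 median was 0.03 in batch 1, 0.33 in batch 2 and -0.01 without WT replicates 5 and 6, and let-7a-5p stood at 231 in WT replicate 5 against 1232 to 1852 in the other WT tumours. The miR-17-92 clusters had a median of 0.02 over 10 members (camera adjusted p = 0.942), with 1 higher adjusted over the list alone, miR-18a-5p. The miR-200 family (median -0.01 over 7) and the intestinal epithelium list (median 0.06 and mean -0.07 over 7) also had a camera adjusted p of 0.942. In these lists miR-200a-3p had 6999 ± 601 in WT and 7510 ± 1290 in G12D, and miR-375-3p had 7442 ± 1059 and 6017 ± 1421. The 13 p53-responsive and tumour suppressor miRNAs had a median of -0.08 (camera adjusted p = 0.553), with miR-29a-3p at 963 ± 80.4 in WT and 805 ± 82.4 in G12D. The smooth muscle and fibroblast list, a marker of other cell types, had a median of 0.08, a mean of 0.17 and a test direction of lower over 9 members (camera adjusted p = 0.942). Its most abundant member, the muscle miRNA miR-133a-3p, had 561 ± 375 in WT and 220 ± 77.4 in G12D. The list median was 0.60 in batch 1 and -0.21 in batch 2. Of the endothelium list 3 miRNAs were tested, too few for the list test, with log2 fold changes of 0.31 for miR-126a-3p and -0.06 for miR-139-5p.

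Ago2-bound sites on mRNA were given as peaks called per genotype. The WT list held 2186 peaks and the G12D list 7569, both with a median width of 56 bases. Of the WT peaks, 92.7% (Wilson 95% interval 91.5% to 93.7%) overlapped a G12D peak on the same strand by at least 1 base, and 26.8% of the G12D peaks (25.8% to 27.8%) overlapped a WT peak. The merged list had 7730 peaks, of which 2029 came from both lists, 161 from the WT list alone and 5540 from the G12D list alone. The lists were made from pooled calls of libraries that differed in depth, so their lengths were not tested.

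Of 7585 annotated peaks, 51.9% lay in or just beyond 3' UTRs, 32.2% in exons, 12.1% in introns and 3.74% in or just before 5' UTRs, and 3933 genes were named. Of 28 colon epithelium genes fixed in advance, 23 had a peak, among them the mucin Muc2, the keratins Krt8 and Krt19 and the intestinal transcription factor Cdx2. Of 25 leukocyte genes 1 had a peak, the antigen-presenting gene H2-Eb1 (Fisher's exact test against the epithelial list, adjusted p = 1.29e-08). Of 17 endothelial and nerve genes 1 had a peak, the receptor Ret (exact adjusted p = 1.14e-06), and of 26 fibroblast and smooth muscle genes 12 had one, mostly collagens (exact adjusted p = 0.00965). Peaks were also found on 20 of 30 Wnt target genes, 19 of 28 genes of MAPK output and feedback, 15 of 28 of the Ras pathway, 19 of 27 of the miRNA machinery, 11 of 27 of TGF-beta and EMT, 21 of 30 let-7 targets and 15 of 27 cell cycle genes.

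The peak of highest mean value lay in an intron of Gphn (chromosome 12, 78351067 to 78351125, GRCm38), with 5818 ± 6814 normalised counts in WT and 3581 ± 1112 in G12D (SD, n = 6 each). The next were on the ribosomal RNA gene n-R5-8s1, an unannotated stretch of chromosome 13 (44869955 to 44870023), Muc2, Myc, Actb, Cyfip1, Gm26561, Muc3 and Rnu12. The Muc2 peak, in an exon on chromosome 7 (141691355 to 141691407), had 2820 ± 3096 in WT and 2323 ± 2567 in G12D.

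The comparison of peaks asked where Ago2 signal differed between the genotypes. The mRNA libraries first differed as a whole. Of the 7730 merged peaks, 5540 came from the G12D list alone and 161 from the WT list alone. The set of peaks therefore leans toward sites with high signal in G12D, and how far this raised the values below was not tested. The median log2 fold change over 7527 tested peaks was 1.33 higher in G12D, so values of single peaks are given below as they are and also relative to this median. It was 0.44 in batch 1, 2.24 in batch 2 and 0.38 without WT replicates 5 and 6, and 0.60 with TMM factors. The ratio of a library's own size factor to that of the deposited values, a measure of its overall peak signal, was 0.805 ± 0.448 in WT and 1.56 ± 0.468 in G12D (SD, n = 6 each, exact permutation p = 0.0238, adjusted p = 0.155 over 13 library measures). With labels exchanged only within batches, the exact p was 0.005 and the adjusted p 0.065, with every G12D library above every WT library of its batch. The WT mean was 1.02, the exact p 0.1 and the adjusted p 0.526 without WT replicates 5 and 6. Within batch 1 the means were 0.835 and 1.16, and within batch 2 they were 0.775 and 1.97, each with an exact p of 0.1, the smallest that 3 against 3 can give.

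**Figure D2:**
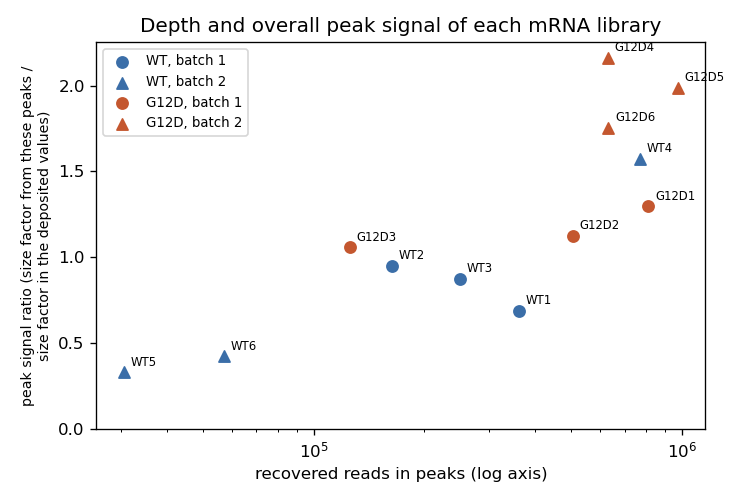
Overall peak signal of each mRNA library (ratio of size factors) against its reads recovered in peaks (log axis), with colours for genotype, circles for batch 1 and triangles for batch 2. WT replicates 5 and 6 have the fewest reads, 30607 and 57037, and the lowest ratios, 0.328 and 0.422.

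The most abundant peak of a Wnt target and let-7 target gene, in the 3' UTR of Myc (chromosome 15, 61990008 to 61990078), had 1092 ± 834 in WT and 3968 ± 2669 in G12D, a log2 fold change of 1.83 (SE 0.49), or 0.50 relative to all peaks. The peak in the 3' UTR of Ereg, an EGF receptor ligand among the MAPK outputs (chromosome 5, 91093341 to 91093397), had 315 ± 284 and 1087 ± 454, 1.51 relative to all peaks. An exonic peak of the cell cycle gene Ccnd1 (chromosome 7, 144934023 to 144934080) had 342 ± 269 and 920 ± 373, 1.00 relative. The 3' UTR peak of Cdx2 (chromosome 5, 147301388 to 147301449) had 8.52 ± 7.28 and 73.1 ± 52.9, 1.81 relative. Peaks of Erbb3, Tnrc6a, Acvr1b, Ccnd2, Ret, Col4a2 and Col5a2 also lay above the median, by 1.16, 0.71, 1.27, 1.08, 0.88, 1.63 and 1.52. Peaks of Cdx2, Erbb3, Tnrc6a, Acvr1b, Ccnd2 and Col5a2 were named only for the smallest p of their list, a choice that favours large changes. Those of Actb, Tnrc6b, Muc2 and Gphn lay below it, at -0.01, -0.47, -1.11 and -1.51, and those of Skil and H2-Eb1 lay at 0.22 and 0.11. Without WT replicates 5 and 6, and relative to the median of that fit, Myc stood at 0.91, Ereg at 0.79, Ccnd1 at 0.51, Acvr1b at 0.80, Ret at 0.54, Col4a2 at 0.96, Skil at 0.14, H2-Eb1 at -0.23, Actb at 0.16, Tnrc6b at -0.23 and Gphn at -0.40. The log2 fold change of Ereg was 1.12 in batch 1 and 4.56 in batch 2.

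Ago2 had 8 peaks, 6 of them in its 3' UTR, with log2 fold changes of 0.93 to 2.04, or -0.40 to 0.71 relative to all peaks. Without WT replicates 5 and 6 the relative values of the Ago2 peaks were -0.40 to 1.01. None of these Ago2 peaks passed in limma (0.108 was their smallest adjusted p), while DESeq2 called 1 of them, in the 3' UTR (log2 fold change 2.00, adjusted p = 0.0118). Apc had no peak in the table.

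No peak passed the limma threshold between genotypes, with 2700 higher and 13 lower in G12D at an unadjusted p under 0.05. Without WT replicate 4 the same test gave 3391 higher and 13 lower, and without WT replicates 5 and 6 it gave 3 higher. Leaving out WT replicate 4 leaves the shallow WT replicates 5 and 6 as the only WT libraries of batch 2. The 3391 calls therefore do not tell the genotype from the low depth of those libraries. edgeR and DESeq2 gave between 10 and 782 peaks, and the direction depended on the tool and on the scaling. edgeR gave 4 higher and 6 lower, and edgeR with TMM factors 1 and 11. DESeq2 gave 755 higher and 27 lower with the deposited size factors, 158 and 12 without WT replicates 5 and 6, and 44 and 75 with size factors estimated on these peaks. limma with library quality weights gave 815 and 38, and limma with a pseudocount of 5 gave 506 and 7. Batch 2 alone, whose WT libraries include the shallow WT replicates 5 and 6, gave 234 higher. Batch 1 alone gave 0, with 542 higher and 25 lower unadjusted.

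The authors' deposited table of peaks holds the 755 higher and 27 lower calls that the DESeq2 fit returned. The rule for named peaks was applied to the authors' deposited table after its values were seen. In the authors' deposited table, the peaks with the largest positive log2 fold changes were on Msn, Clasrp, Ly6g, Abcb1a, Kat6a, Lsm8, Kbtbd11, Srd5a1, Phlda2 and Zc3h11a, from 3.40 for the cytoskeletal linker Msn to 2.77 for Phlda2 and Zc3h11a. The largest negative log2 fold changes in the authors' deposited table were on Spock2 (-3.97), RP23-189B9.3 (-3.34), the secreted Wnt inhibitor Wif1 (-2.95), the metallothionein Mt3 (-2.67), Dst (-2.48), Arhgef26 (-2.27), the transcription factor Prox1 (-2.08) and AC130827.2 (-1.85), with 2 unannotated peaks. Myc stood at 1.70 with an adjusted p of 0.00615 in the authors' deposited table.

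**Figure D3:**
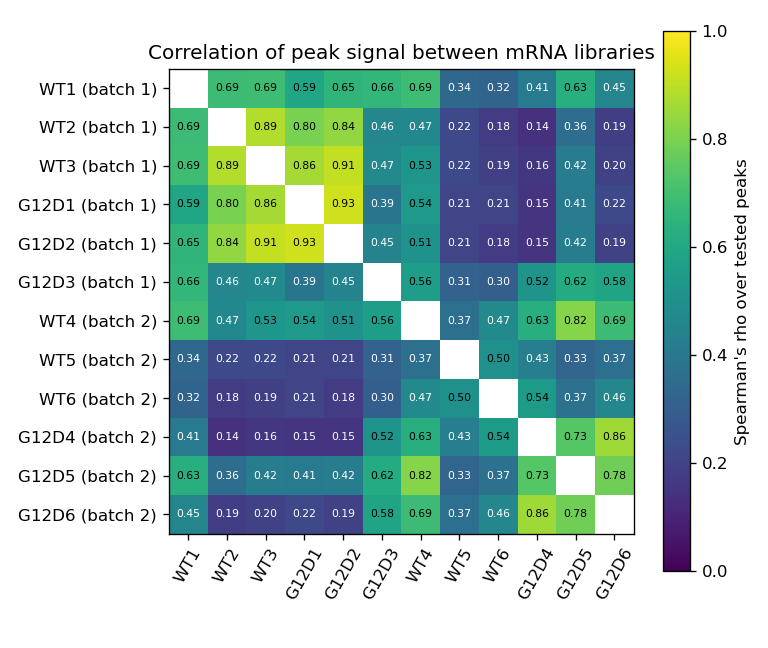
Spearman's rho of peak signal over the tested peaks between each pair of mRNA libraries, ordered by batch and genotype. Pairs from 1 batch had a mean rho of 0.646 within a genotype and 0.605 across genotypes, and pairs from different batches 0.357 and 0.333.

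The mRNA libraries resembled each other by batch more than by genotype. For 11 of the 12 the closest library came from the same batch, and for 7 of the 12 it had the same genotype. The exception was WT replicate 1, whose closest library was WT replicate 4 of batch 2 (rho 0.689). G12D replicate 3 of batch 1 had a rho of 0.519 to 0.617 with WT replicate 4 and G12D replicates 4 to 6 of batch 2, of 0.301 and 0.314 with WT replicates 6 and 5 of that batch, of 0.387 to 0.473 with WT replicates 2 and 3 and G12D replicates 1 and 2 of its own batch, and of 0.662 with WT replicate 1, its closest library. In the miRNA libraries rho was high throughout, with a mean of 0.940 over all 66 pairs, from 0.873 to 0.981.

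Of 9 gene lists with at least 5 peaks tested, the Wnt target genes stood apart. Their 68 peaks had a median log2 fold change of 1.07, which lay 0.26 below that of all peaks, and camera with a preset correlation placed them lower (adjusted p = 1.09e-05). With an estimated correlation the adjusted p was 0.990. The median relative to all peaks was -0.27 in batch 1, -0.25 in batch 2 and -0.27 without WT replicates 5 and 6. Their members went both ways. No peak of the list passed in limma over all peaks, and DESeq2 called 9 higher and 3 lower. In limma 2 were higher when adjusted over the list alone, the Myc 3' UTR peak and an intronic peak of the receptor Ephb2. The Ephb2 peak had a log2 fold change of 2.95 (SE 0.79), or 1.62 relative to all peaks. It was a low peak, with a mean of 12.3 normalised counts and 3.56 ± 6.62 in WT. Without WT replicates 5 and 6 its log2 fold change was 1.81, or 1.43 relative to the median of that fit. The peaks on the other side named here were chosen after their values were seen. The Wif1 peak, in an exon on chromosome 10 (121090136 to 121090194), had a log2 fold change of -2.49 (SE 0.74), with -2.04 in batch 1 and -2.95 in batch 2. Prox1 had an exonic peak at 156 ± 200 and 23.4 ± 11.8, Dkk2 an intronic peak at 60.1 ± 82.7 and 13.8 ± 15.0, and Notum an exonic peak at 66.9 ± 102 and 18.5 ± 14.6. Nkd1 had a 3' UTR peak at 38.4 ± 19.8 and 20.6 ± 9.79. None of these peaks passed in limma over all peaks or over the list alone, while DESeq2 called those of Wif1 (adjusted p = 0.00287) and Prox1 (adjusted p = 0.0307). Without WT replicates 5 and 6 the log2 fold change went from -1.59 to -3.15 for Dkk2 and from -1.03 to -0.59 for the Notum exon in limma. Leaving out G12D replicate 3 gave 3 gene lists past the threshold, and leaving out G12D replicate 4, WT replicate 2 or WT replicate 4 gave 2.

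No other gene list passed. Relative to all peaks, the medians were -0.07 for MAPK output and feedback (58 peaks, camera adjusted p = 0.474), 0.17 for the Ras pathway (33 peaks, 0.702), 0.05 for the miRNA machinery (73 peaks, 0.709), 0.00 for TGF-beta and EMT (27 peaks, 0.965), 0.19 for let-7 targets (80 peaks, 0.122), 0.08 for the cell cycle (52 peaks, 0.349), -0.16 for colon epithelium (84 peaks, 0.474) and 0.27 for fibroblast and smooth muscle genes (29 peaks, 0.258). The direction turned between batch 1 and batch 2 for fibroblast and smooth muscle genes (0.62 and -0.17), colon epithelium (-0.40 and 0.02), MAPK output and feedback (-0.28 and 0.08), the miRNA machinery (0.04 and -0.09) and let-7 targets (0.28 and -0.01). Adjusted over the list alone in limma, 1 peak of the colon epithelium list (Cdx2) and 2 of the fibroblast and smooth muscle list were higher, and none in the other 6 lists. Over all peaks, DESeq2 called 6 higher and 1 lower in the MAPK list, 3 higher in the Ras pathway list (Erbb3 among them), 3 in the machinery list, 3 in the TGF-beta and EMT list (Acvr1b among them), 13 in the let-7 target list (Myc among them), 7 in the cell cycle list (Ccnd2 among them), 6 in the colon epithelium list and 2 in the fibroblast and smooth muscle list. Without WT replicates 5 and 6 the colon epithelium list had an adjusted p of 0.0151. Over all 12 tumours its adjusted p was 0.990 with an estimated correlation. The leukocyte list had 3 peaks tested and the endothelium and nerve list 2, too few for the list test.

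The next comparison asked whether Ago2 sites follow the miRNAs. Of the annotated peaks, 55.6% (Wilson 95% interval 54.5% to 56.7%) held a 7mer-m8 or 8mer seed site in the authors' annotation. Annotated sites of the 7mer-A1 class were not counted, here or in the other results on sites and families. The share was highest in introns, at 60.6%, and was 56.5% in 3' UTRs, 52.7% in exons and 51.4% in 5' UTRs. The let-7 family had the most peaks, 684, followed by miR-15/16 with 401, the family of miR-200b, miR-200c and miR-429 with 380, miR-29 with 379 and miR-17 with 378, while miR-21, whose member was the most abundant single miRNA, had 69. Across 36 families, the number of peaks with a site correlated with the mean level of the family's miRNAs (Pearson r = 0.49, permutation p = 0.00214, adjusted p = 0.00428; Spearman rho = 0.54, permutation p = 0.000820). Without the 2 families farthest from the median level r was 0.37. This relation is across families, which are not independent replicates. No shuffled background was made, so how common each seed motif is by itself was not taken into account. Each of the 36 families was marked in advance as expressed or as of blood, so no other family served as a control.

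Peaks with a miR-31 site lay lowest in G12D relative to all peaks. miR-31-5p is a miRNA raised in colorectal tumours and inflamed gut. Its 61 peaks had a median 0.84 below that of all peaks (camera adjusted p = 2.42e-14, and adjusted p = 0.995 with an estimated correlation). The median relative to all peaks was -0.45 in batch 1, -1.07 in batch 2 and -0.69 without WT replicates 5 and 6. miR-31-5p itself had 4776 ± 2386 in WT and 3013 ± 1619 in G12D, a log2 fold change of -0.61 (SE 0.42, adjusted p = 0.489). Sites of miR-182 also lay lower, by 0.32 (camera adjusted p = 0.00204), while miR-182-5p had 582 ± 365 in WT and 792 ± 245 in G12D. The log2 fold change of miR-182-5p was 0.84, and 0.10 without WT replicates 5 and 6. Sites of miR-7 (0.36, camera adjusted p = 0.00501), miR-29 (0.22, 0.00979), miR-15/16 (0.20, 0.00948) and miR-24 (0.15, 0.0215) lay higher. These 6 were the families past the threshold of 35 tested, and with an estimated correlation the adjusted p was 0.995 for each of them. Without WT replicates 5 and 6, miR-29 had an adjusted p of 0.334 and miR-182 of 0.0869. The shift in batch 1 and in batch 2 was 0.29 and -0.07 for miR-24 sites, -0.14 and -0.52 for miR-182, 0.13 and 0.59 for miR-7, 0.12 and 0.42 for miR-29 and 0.15 and 0.32 for miR-15/16. It was, when WT replicates 5 and 6 were left out, -0.21 for miR-182, 0.17 for miR-7, 0.07 for miR-29, 0.13 for miR-15/16 and 0.24 for miR-24.

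**Figure D4:**
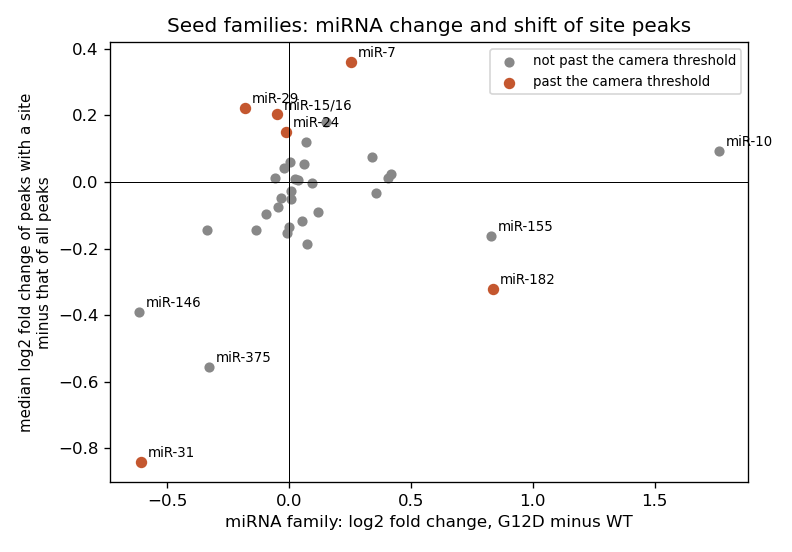
Median log2 fold change of the peaks with a family's site minus that of all peaks, against the log2 fold change of the family's miRNAs (G12D minus WT), with 1 point per family and the 6 families past the camera threshold in orange. miR-31 lies lowest, at -0.84, and miR-7 highest, at 0.36.

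Across the 35 families, the shift of the peaks was not shown to follow the change of the miRNA (Pearson r = 0.33, permutation p = 0.0594; Spearman rho = 0.27, permutation p = 0.121). Without the 2 families farthest from the median change, r was 0.51. In the miR-146 family, whose miRNAs summed to 5517 ± 528 in WT and 3606 ± 396 in G12D, 29 peaks had a median of -0.39 relative to all peaks (camera adjusted p = 0.157). That median was -0.05 in batch 1, -0.58 in batch 2 and -0.07 without WT replicates 5 and 6.

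Tumour by tumour, the relative signal of the miR-31 site peaks correlated with the tumour's own miR-31-5p level. Over the 12 tumours Pearson r was 0.83 (permutation p = 0.000370, adjusted p = 0.0130 over 35 families) and Spearman rho was 0.84 (permutation p = 0.00107, adjusted p = 0.0374). Without the 2 tumours farthest from the median level, WT replicates 5 and 6, r was 0.93. It was 0.89 in batch 1, 0.85 in batch 2, 0.75 within the 6 WT tumours and 0.996 within the 6 G12D tumours. miR-31 was looked at on its own after its shift had been seen. For the other 34 families the correlation did not pass the adjusted threshold. The median r over the 35 was 0.28, and 22 were positive.

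**Figure D5:**
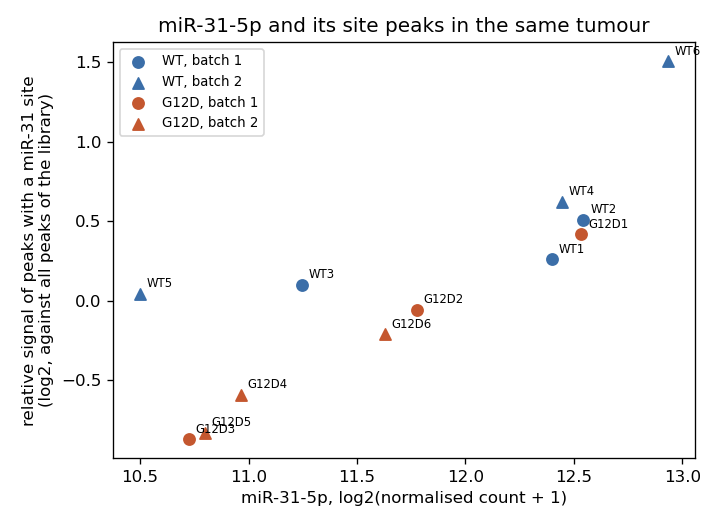
Relative signal of the peaks with a miR-31 site (log2, against all peaks of the library) against miR-31-5p (log2 of the normalised count plus 1) in each of the 12 tumours, with colours for genotype, circles for batch 1 and triangles for batch 2. The lowest relative signal is that of G12D replicate 3, -0.87 at a level of 10.72, and the highest that of WT replicate 6, 1.51 at 12.94, while WT replicate 5 has the lowest level, 10.50, at a signal of 0.04.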

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

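The tests of the general rise of peak signal, of leukocytes, of smooth muscle and of the shallow libraries as the source of the miR-31 shift were chosen only after the result was seen, while the split tests were planned. Leaving out WT replicates 5 and 6 was also added after the data had been seen, though what it would show for the called miRNAs was written down first, and the miR-31 test was written down after the group values of miR-31 and its peaks had been seen.

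In 19 of 162 groups of 6 tumours, 1 tumour lay far from the other 5 by Dixon's test. Chance alone marks about 1 in 20 groups if values are normally distributed and groups independent. These groups were untransformed counts and shares, several from the same library, so the 19 need not be separate cases. WT replicate 5 was the far tumour 8 times and WT replicate 4 was it 5 times. In WT replicate 5 the 10 strongest peaks held 47.8% of the signal (6.15% to 14.2% in the other WT tumours). Its share of signal was 28.3% in 3' UTRs (45.9% to 48.3%), 24.5% in exons (38.5% to 39.6%), 21.6% in introns (5.50% to 8.30%), 23.0% in unannotated peaks (1.95% to 4.47%) and 29.98% in peaks with a seed site (63.4% to 70.3%). The Gphn peak stood at 19474 in this tumour (1608 to 5037) and the unannotated peak on chromosome 13 at 16883 (699 to 3347). WT replicate 4, the deepest WT library, was far above the other WT tumours for peaks of Myc with 2762 (496 to 986), Tnrc6a with 428 (22.6 to 99.3), H2-Eb1 with 66.2 (0 to 17.1), Acvr1b with 33.1 (0 to 7.34) and Ephb2 with 16.8 (0 to 3.43). In G12D replicate 1, miR-194-5p stood at 11407 (13345 to 14291 in the other G12D tumours) and the Ccnd1 peak at 1641 (597 to 961). In G12D replicate 3, the intron share was 10.4% (6.46% to 7.81%) and the share with a seed site 63.1% (68.0% to 70.8%). An Ago2 3' UTR peak stood at 26.3 in G12D replicate 5 (6.94 to 13.5), and let-7i-5p at 6596 in WT replicate 2 (5149 to 5638).

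Peak signal was higher in G12D over most peaks, with a median log2 fold change of 1.33. Most peaks, 5540 of 7730, were called in the G12D list alone. That choice of peaks favours a rise in G12D, and its part in the median and in the ratio below was not tested. Without the 2 shallow WT libraries the median was 0.379, so these libraries could account for most of the rise in limma, while in DESeq2 it went from 0.854 to 0.45. With size factors estimated on the peaks the median in DESeq2 was 0.0702, but such factors bring the median near 0 by construction, so whether the library size factors made the rise cannot be told apart. In 0 of 18 pairs from the same batch did a WT library have the higher overall peak signal, but that ratio restates the rise per library, so an effect of the genotype cannot be told apart from a difference in library yield.

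The fall of miR-146a-5p, miR-146b-5p and other miRNAs might come from fewer leukocytes in G12D tumours, and this cannot be told apart because the 4 other leukocyte miRNAs went both ways around a median of 0.0340. Less smooth muscle and fibroblast RNA cannot be told apart either, as that list had a median of 0.0826 with members on both sides. Without WT replicates 5 and 6, 100% of the 11 called miRNAs kept their sign at an unadjusted p under 0.05. That is a mild test, as the 11 were called with these tumours included. At the adjusted limma threshold 9 of the 11 stayed, so for those 9 the 2 tumours were not the whole source. miR-193a-3p (limma adjusted p = 0.154) and miR-672-5p (0.142) did not stay. Relabelling did not give such a count: of 100 splits of the 12 tumours into 6 and 6, the real one included, 1 had 11 or more miRNAs past the threshold, and the highest other count was 2. These splits were drawn without balancing the batches, unlike the real groups.

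The peaks with a miR-31 site lay lower in G12D relative to all peaks, and their relative signal followed the miR-31 level of the same tumour (r = 0.833), which could account for the shift. The 2 shallow WT libraries were excluded as its whole source, since the shift was -0.692 without them. Of 100 splits, drawn without balancing the batches, 7 had a result as extreme as the real one, so a tie to the genotype was not shown. Levels of miR-31 that vary between tumours for any reason may be enough.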

How the results depend on the processing

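The settings that leave out WT replicates 5 and 6, weight libraries or take factors from the peaks, and, for lists and families, those that leave out 1 tumour, use 1 batch or use 8mers, were chosen only after the result was seen. All 11 called miRNAs kept their direction in all 27 settings. For miRNAs the count was 31 with DESeq2, 21 with DESeq2 without WT replicates 5 and 6, 17 with library quality weights, 6 with no batch term, 1 in batch 1, 0 in batch 2 (17 higher and 25 lower unadjusted) and 5 to 16 leaving out 1 tumour. For peaks, 0 in limma became 782 with DESeq2, 170 with DESeq2 without WT replicates 5 and 6, 119 with DESeq2 and size factors from the peaks, 10 with edgeR, 12 with edgeR and TMM factors, 853 with library quality weights, 513 with a pseudocount of 5, 234 in batch 2, 3 without WT replicates 5 and 6 and 0 to 3404 leaving out 1 tumour. Rescaling to an equal total gave 0 (708 higher and 83 lower unadjusted) and TMM in limma 0 (705 and 102). For miRNA lists, 1 became 2 in batch 1, 0 in batch 2, 0 with an estimated correlation, 0 with fry, 2 without WT replicates 5 and 6 and 0 to 1 leaving out 1 tumour. For gene lists, 1 became 5 in batch 1, 0 with an estimated correlation, 0 with fry, 2 without WT replicates 5 and 6 and 1 to 3 leaving out 1 tumour. For seed families, 6 became 1 with 8mer sites, 2 in batch 1, 3 in 3' UTRs, 0 with an estimated correlation, 0 with fry and 4 to 7 leaving out 1 tumour. With fry, which does not compare a list with other peaks, the direction turned for the Wnt target genes (adjusted p = 0.147), miR-31 (0.459) and miR-182 (0.129). The share of peaks with a seed site was 30.7% for 8mers and 61.5% in the WT list, and the overlap of WT peaks 97.7% by the top-scored peaks. The cause was not tested for these differences, save that batches and 8mers leave fewer samples or sites. Of the other values, 3000 were the same, 103 stronger, 114 weaker, 1 moved and 3 turned. A change of sign in a feature past the threshold in neither setting counts as the same.

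With a replicate block 6 miRNAs passed, 5 of them among the 11, and 0 peaks. Same-numbered tumours did not all correlate, with deviations from group means at 0.0747 to 0.457 for miRNAs and -0.114 to 0.649 for peaks, and not every tumour was closest to its own number, so the numbers were not taken to pair tumours. Settings that use input libraries were not run. WT replicate 5 had 30607 reads in the peaks, so its values of single peaks rest on few reads. Whether depth limited the number of calls was not settled. In limma, leaving out WT replicate 5 gave 0 peaks, and leaving out WT replicate 4, the deepest WT library, gave 3404.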

Other observations

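The genes and peaks of this part, and the tests beside them, were chosen only after the result was seen, except the splits of the tumours. Beside miR-99a-5p, let-7c-5p had a log2 fold change of -0.02 (SE 0.08) and miR-125b-5p of 0.37 (SE 0.50), and both are made from more than 1 locus. miR-449c-5p, a cluster partner of miR-449a-5p, stood at -1.38 (SE 0.41, adjusted p = 0.0857 in limma), and miR-34c-5p, of the same seed family, at -0.40 (SE 0.41). Differences between these miRNAs were not tested. Among the peaks with a miR-31 site, relative to all peaks, those of the Wnt inhibitor Dkk2 (-2.92), the sodium-hydrogen exchanger Slc9a3 (-2.07), the cyclin Ccni (-1.13), the tight junction gene Cldn4 (-1.02), Stk40 (-0.69) and the hypoxia regulator Hif1an (-0.21) lay lower, and that of Prr5 lay higher (1.14).

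A peak on Xist, the RNA of the inactive X chromosome, stood at 103, 188, 58.2, 19.3, 0 and 2.41 in WT replicates 1 to 6 and at 0, 0, 74.1, 412, 383.7 and 604 in G12D replicates 1 to 6. A peak on the Y-linked gene Uty stood at 168 in WT replicate 3, 191 in G12D replicate 1, 174 in G12D replicate 2, 22.2 in WT replicate 4 and 6.94 in G12D replicate 3, with 3.79 or less in the others. Summed over the peaks of each gene, Xist and Uty were both above 0 in 9 of the 12 libraries. Their values were 192 and 3.43, 358 and 3.79, 102 and 177, 33.1 and 61.7, 9.06 and 4.53, and 12.1 and 2.41 in WT replicates 1 to 6, and 0 and 213, 0 and 197, 99.5 and 48.6, 615 and 11.97, 599 and 0, and 876 and 3.55 in G12D replicates 1 to 6. Some low values rest on very few reads: Uty in WT replicates 5 and 6, at 4.53 and 2.41, was 1 read in each. Over all 12 libraries the Xist and Uty values did not follow the genotype or the batch labels in 1 direction. Within G12D, Xist was higher and Uty lower in every batch 2 library than in every batch 1 library. Within WT, Xist was lower in every batch 2 library. Within batch 2, Xist was higher in every G12D library than in every WT library, so it cannot be told apart from genotype there. Within batch 1 the summed Xist was lower in every G12D library, though G12D replicate 3, at 99.5, lay close to WT replicate 3, at 102. Sex was not a covariate in any test, so its part in the differences between genotypes was not tested. Whether a library held RNA of more than 1 animal, or another sample than its label says, was not tested, so the identity of these samples is in doubt to that extent. Explanations for groups of mRNA libraries that cross genotype were written down and then dropped without a test, after these values had been looked at.

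The tumours were also split into 6 and 6 in 100 ways, the real one included, to see how often each count arises. A count as large as the real 1 miRNA list arose in 77 splits (highest 4) and as large as the real 1 gene list in 61 (highest 5). For the 6 seed families this held in 23 splits (highest 13), and for peaks, where the real count was 0, in all 100, with a highest count of 3292. So the counts of lists and families could arise from the structure among these tumours without the genotype. The splits were first drawn as 99 and redrawn because the split that equals the batches could not be fitted, with the same reading.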
